A study of Homo sapiens with 74 samples.

How the data were processed

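In situ Hi-C was carried out in Hap1 (5 libraries) and GM12878 (6 libraries), and Hi-C with hybrid capture in Hap1 (63 libraries), 74 libraries in all, per the labels. Per the labels' protocols, crosslinked nuclei were permeabilised, DNA was cut, ends were filled in with a biotinylated base and ligated in place, and ligated fragments were recovered on streptavidin beads and sequenced. Groups were formed from the cell line and protocol labels. Only the authors' loop list and contact domain list for Hap1 were used here. Each is a single call set that was read as pooled over the Hap1 in situ Hi-C libraries, since its columns name no library, and the depth of each library is unknown here. GM12878 and Hi-C2 libraries were not analysed here, and 0 further columns of per-sample values were present.

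Per the file headers, the loop list gives for each loop the observed contact count, 4 expected values from the lower-left, donut, horizontal and vertical neighbourhoods of the pixel, 4 FDR values, the number of pixels merged, the centroid and the radius. The observed counts deposited by the authors were whole numbers from 12 to 1119. The expected values were deposited on the scale of the counts. The FDR values deposited by the authors, which are p-values adjusted for multiple tests, reached at most 0.0993 in any of the 4 columns, so every listed loop had passed a threshold at or above that. The domain list has 5 unnamed score columns deposited by the authors. The first column, from 0.0626 to 1.879, was read as the corner score of the domain caller from its position and range, which is not stated in the sources used here. The other score columns enter no result here. The last 2 were never below 0.4, so the authors' list was filtered on them or they are bounded by construction.

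The submitters' processing notes name BWA and the mouse build mm9. The lists hold 23 human chromosomes, so mm9 cannot be their build. Their coordinates pass the last gene of GRCh38.p14 on 8 of the 23 chromosomes, by up to 2.40 Mb, and pass the length of GRCh37 on 0 chromosomes. The human build itself is not given in the sources used here. The only annotation on hand was of GRCh38.p14, so no gene was assigned to a loop, and no sequence was scanned. Planned comparisons that need one of these were not run: the share of convergent CTCF motif pairs, loop strength and loop length by motif orientation, start sites of protein-coding genes in anchors, and gene lists at anchors. Loop density was set against domain density, the fallback fixed before the data were examined.

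Loop length was the distance between anchor centres. A domain had a corner loop where the centres of a loop's anchors lay within the smaller of 50 kb and 0.2 of the domain length from its start and end. The null shifted all loops around each chromosome 1000 times. Differences between domains with and without a corner loop were tested by 100000 permutations, for the score within 10 length classes and for loop ratios within 5 length classes per anchor size. Alternatives of these differences and of the density correlation used 10000 permutations, those of pairs of loops 300, and those of corner shares, sides and ends 1000. Where each chromosome was left out in turn, 1000 permutations or shifts were used. Pairs of loops counted as sharing an anchor within 25 kb. Overlapping anchors were merged. Sides of loop ends were permuted within chromosomes over the ends at shared anchors. Neighbouring ends had centres at most 30 kb apart and did not overlap, and right ends were shifted in steps of 5 kb. Chromosome length was the span of listed features without empty stretches of over 3 Mb. Standard errors came from a jackknife that left out each of the 23 chromosomes. Intervals on shares were exact Clopper-Pearson 95% intervals. Intervals on observed counts and their ratios were exact Poisson intervals, which cover counting error only and take expected values as known.

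The local background of loops of at most 2 Mb was the log2 donut expected value minus a quadratic fit on log2 length, fitted for each anchor size. On each chromosome the stretch of at least 20 loops that stood farthest from the rest was found by a scan over all start and end loops. Its standard error came from 1000 bootstraps of blocks of 1 Mb. Stretches of the same width were laid on all chromosomes at steps of 1 Mb.

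Loops named in the text were fixed by rule before the data were examined: the 10 with the highest observed over donut ratio among those with at least 50 contacts, the 10 merged anchors in the most loops, and the 10 longest. The 3 Mb limit, the comparisons of sides and ends and loop ratios at domain corners were chosen after the data were seen. So were named domains, windows and the local background. Alternatives tried were the matching distance, stricter FDR values (0.01 or less in all 4 columns), domains at or above the median score, the distance for a shared anchor, length limits, other backgrounds and leaving out chromosomes.

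The code was tested on simulated data. Of 1500 corner loops planted well within the matching distance in 4332 domains, 1500 were found, which checks the code only. Of the other domains 2.37% were called, against 2.35% under shifting. A planted score difference of 0.1 between domains with and without a corner loop was estimated as 0.109. Of 200 simulations without a difference, 9 gave p under 0.05. In those the score depended on length only through the length class, so they leave out length differences within a class. Counts of interleaved and nested pairs matched enumeration (445 and 221). A planted one-sided share of 80% of anchors was counted as 80%. A background shift planted over loops 100 to 159 of a chromosome was found from loop 103 to 159. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.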

Results

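The series measured the folding of human chromosomes by in situ Hi-C, which ligates DNA ends that lie close together in crosslinked nuclei and sequences the junctions, and by a capture form of it that enriches chosen regions by hybridisation (Hi-C2). The 74 libraries fell into 3 groups by cell line and protocol. Hap1, a near-haploid line derived from the chronic myeloid leukaemia line KBM-7, had 5 in situ Hi-C libraries and 63 Hi-C2 libraries. GM12878, a lymphoblastoid B cell line, had 6 in situ Hi-C libraries. The values below come from the authors' loop list and contact domain list for Hap1, each a single call set whose columns name no library, so there is no replicate to set them against. The errors given are jackknife standard errors over 23 chromosomes or exact binomial 95% confidence intervals, and both leave out the spread between cultures. The design text names genome editing, but the labels do not say which libraries came from edited cells, so cells before and after editing were not compared here, nor were Hap1 and GM12878. Coordinates are those of the authors' lists, counted from 1. Their human build is not given in the sources used here, so loops are named by position and not by gene.

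The Hap1 genome held 8334 loops, that is, pairs of loci with more contacts than their surroundings, and 4332 contact domains, intervals whose loci contact one another more than loci outside. Loops were short. Their median length was 300 kb, with quartiles of 160 kb and 540 kb, and 92.1% spanned less than 1 Mb. Contact domains had a median length of 260 kb, with quartiles of 190 kb and 390 kb, and 774 of them (17.9%, interval 16.7% to 19.04%) lay inside a larger domain. A loop had a median of 66 observed contacts, for which Poisson counting error alone gives a 95% interval of 51.04 to 83.97. Its contacts were a median of 2.74 times those expected from the surrounding donut of pixels, with quartiles of 2.32 and 3.45. The ratio fell with anchor size, from a median of 3.44 for the 2781 loops with 5 kb anchors to 2.73 for the 2972 with 10 kb anchors and 2.35 for the 2581 with 25 kb anchors. It changed little with length up to 2 Mb, from a median of 2.49 under 100 kb to 2.90 between 1 and 2 Mb.

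A small group of far longer loops stood apart. There were 50 loops of 2 to 3 Mb, 25 of 3 to 10 Mb and 42 of over 10 Mb. The median ratio was 3.36 at 2 to 3 Mb, 14.1 at 3 to 10 Mb and 104 above 10 Mb, where the median observed count was 24. No listed loop had fewer than 12 observed contacts. Where few contacts are expected, as at long distances, a listed loop must therefore have a high ratio. The expected contacts of the horizontal and vertical neighbourhoods differed by at least 10 times in 27 of the 67 loops of over 3 Mb, among them 7 where the smaller value was 0, and in 1 of the 8267 shorter loops.

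**Figure D1:**
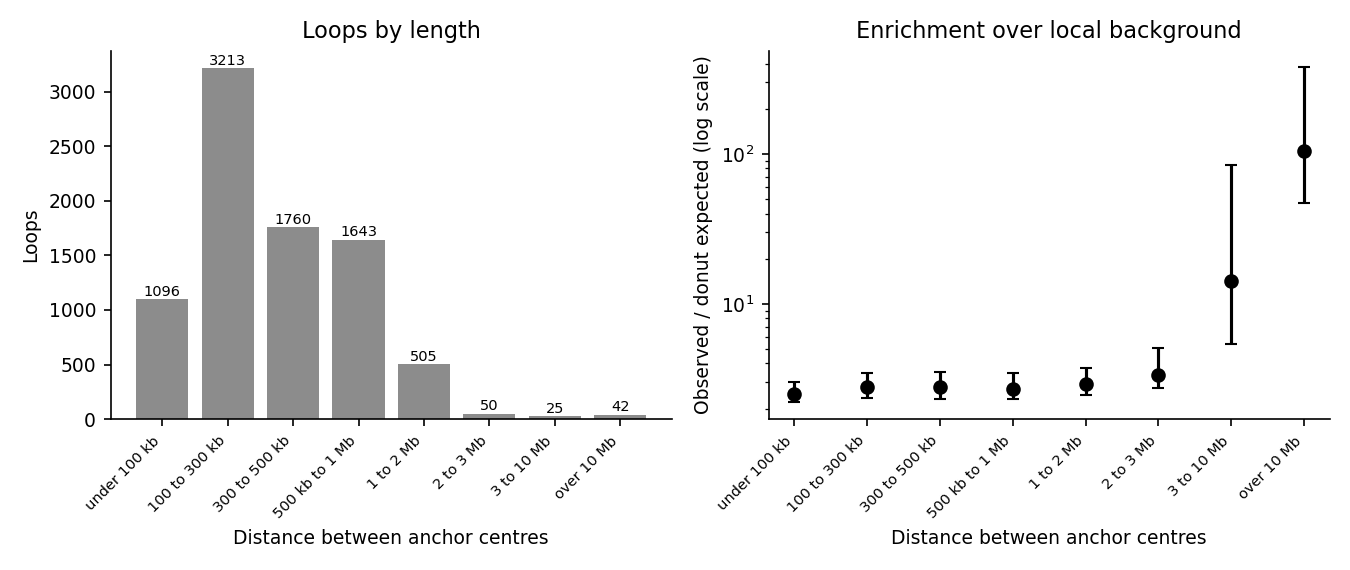
Number of Hap1 loops in each class of distance between anchor centres (left, bars) and observed over donut expected contacts in the same classes on a log axis (right, points are medians and bars run from the lower to the upper quartile). Medians lie between 2.49 and 3.36 up to 3 Mb and reach 104 in the 42 loops of over 10 Mb.

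Of the 10 loops with the highest ratio among those with at least 50 observed contacts, 8 spanned over 10 Mb. The highest joined 101965001 to 101970000 and 128750001 to 128755000 on chromosome 8, with 95 contacts against 0.0789 expected (ratio 1204, counting interval 974 to 1472). On chromosome 9, the pixel joining 92850001 to 92875000 and 130875001 to 130900000 had a ratio of 318. On chromosome 17, the pixel joining 43650001 to 43675000 and 62900001 to 62925000 had a ratio of 164, or 98.4 over the lower-left neighbourhood. The most contacts among these 10, 320, joined 17050001 to 17060000 and 234910001 to 234920000 on chromosome 1 (ratio 111). The remaining 2 were short. On chromosome 10, a loop of 685 kb joined 81295001 to 81300000 and 81980001 to 81985000 (52 contacts, ratio 72.2, counting interval 53.9 to 94.6). Also on chromosome 10, a loop of 705 kb joined 47650001 to 47655000 and 48355001 to 48360000 (75 contacts, ratio 57.2, counting interval 45.01 to 71.7). The 3 Mb limit used next was chosen after the values were seen. Among loops of at most 3 Mb with at least 50 contacts, the next highest joined 75600001 to 75625000 and 78225001 to 78250000 on chromosome 15. It lay in a segment of raised background (84 contacts, ratio 16.8, counting interval 13.4 to 20.8). It was followed by a loop of 990 kb on chromosome 12 from 63265001 to 64260000 (118 contacts, ratio 13.2) and one of 1115 kb on chromosome 16 from 21590001 to 22710000 (134 contacts, ratio 12.8). Over the lower-left neighbourhood in place of the donut, the ratio was 134 for the chromosome 12 loop and 25.1 for the chromosome 16 loop. On chromosome X the highest ratio in this set was 9.98, for a loop of 945 kb from 18405001 to 19355000. The limit of 50 contacts left out loops with higher ratios. Among them was a loop of 2735 kb on chromosome 15 from 28390001 to 31130000 (40 contacts, ratio 710). Its horizontal and vertical expected values, 0.0762 and 0.158 contacts, were also each under 0.05 of those observed.

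The longest loop spanned 218.35 Mb, from 16560001 to 234920000 on chromosome 1, with 21 contacts. The 6 longest loops all ended in the bin from 234900001 to 234925000 on chromosome 1 and began between 16560001 and 17410000. The remaining 4 of the 10 longest spanned 128.5 Mb on chromosome 1, 100.35 Mb on chromosome 9, 98.4 Mb on chromosome 12 and 74.85 Mb on chromosome 3. The chromosome 12 loop, from 26955001 to 125360000, had 23 contacts against 0.00258 expected, a ratio of 8909 (counting interval 5648 to 13368).

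The first question was how loops and contact domains fit together, since a model in which loops are extruded from the chromatin fibre places loops at domain corners. Of the 4332 contact domains, 2062 had a loop joining their start and end (47.6% ± 1.13, jackknife SE, interval 46.1% to 49.1%). Loops shifted around each chromosome met a domain corner in 3.21% of domains (SD 0.366 over 1000 shifts; circular-shift permutation test, one-sided p = 0.001, the smallest 1000 shifts can give). Corner loops were most frequent in domains of middle size. The share was 36.8% in domains of 130 to 190 kb, 55.8% (interval 52.4% to 59.1%) in domains of 300 to 440 kb and 43.6% in domains of 440 to 2860 kb, with a matching distance that was narrower for domains under 250 kb. The share depended on how near the loop had to lie: 31.2% of domains had a loop within the smaller of 25 kb and 0.2 of the domain length, against 1.09% for shifted loops. In the other direction, 2136 of the 8334 loops (25.6%) lay at a domain corner.

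Domains with a corner loop had a higher value in the unnamed column of the authors' list that was read here as the corner score. Their mean corner score, a number the authors' list gives for each domain, was 1.26 (SD 0.261) against 1.10 (SD 0.2597) for domains without, and the difference within 10 classes of domain length was 0.127 ± 0.00649 (permutation test, two-sided p = 1e-05, the smallest 100000 permutations can give). Both lists were read as called from the same contacts. Part of this difference, and of the match of loops to domain corners, may therefore be built in, by an amount that was not tested. The 5 highest scores among domains with a corner loop were close together, from 1.879 for the domain from 12510001 to 12880000 on chromosome 12 and the domain from 52190001 to 52560000 on chromosome 20 to 1.86 for the domain from 98040001 to 98470000 on chromosome 7. Of the 5 longest domains, 4 had no corner loop, among them the longest, of 2860 kb, from 35890001 to 38750000 on chromosome 10 (score 0.241).

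No difference in length held up between domains with and without a corner loop. The mean difference was 0.0042 ± 0.00801 on the log10 scale (permutation test, two-sided p = 0.554). The median was 270 kb with and 250 kb without, while the mean was 339 kb with and 359 kb without, so the measures differed in sign. The sign also turned with the matching distance: the difference was -0.0435 with the smaller of 25 kb and 0.2 of the length and 0.0556 with the smaller of 100 kb and 0.2 of the length.

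Loops at domain corners did not have higher ratios over the local background than other loops of their length and anchor size. Their median ratio was 3.05 against 2.64 elsewhere, but within anchor size and length classes the mean log2 ratio differed by -0.05 ± 0.01 (permutation test, two-sided p = 0.00213). Against the lower-left background in place of the donut it was -0.15 (p = 0.0001, the smallest 10000 permutations can give). Among loops of at most 3 Mb the difference against the donut was -0.01, with p = 0.598. These comparisons were added after the data were seen. The local background may itself differ at a domain corner, so the ratio does not measure the contacts of a loop alone.

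The second question was how loops lie relative to each other, since loops formed along one fibre are expected to nest or lie side by side and not to interleave. Among 12267 pairs of overlapping loops with no shared anchor, 1317 were interleaved and the others nested (10.7% ± 6.22 interleaved). With loop lengths permuted within chromosomes the share was 32.4% (SD 1.30; two-sided permutation p = 0.001, the smallest 1000 permutations can give). The level depended on the loops included. Without chromosome 1 the share was 16.96%, against 40.7% for permuted lengths. Among loops of at most 3 Mb, 1195 of 3265 pairs were interleaved (36.6%), against 53.4% for permuted lengths. Among loops of at most 1 Mb the shares were 42.5% and 60.8%. The interleaved share thus lay below its permuted level at every limit while its level moved with the limit. For loops of at most 3 Mb, permuted lengths gave on average 9349 overlapping pairs, of which 4996 were interleaved. Nested pairs in that set were therefore also fewer than permuted. The lower share there does not by itself show that loops nest in place of interleaving.

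Many anchors took part in several loops, and mostly with partners on the same side. The 8334 loops had 11950 distinct anchors, of which 3468 were used by more than 1 loop (29.02% ± 0.511, interval 28.2% to 29.8%). There were 2509 anchors in 2 loops, 733 in 3, 176 in 4, 38 in 5, 9 in 6 and 3 in 7. Of the 3468 shared anchors, 1458 had all partners to the right, 1500 had all partners to the left and 510 had partners on both sides. The share with partners on one side was 85.3% ± 0.656, against 42.2% (SD 0.821) with sides permuted within chromosomes (two-sided permutation p = 0.001, the smallest 1000 permutations can give). The comparisons of sides in this and the next paragraph were added after the data were seen.

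Where a left end and a right end of loops lay next to each other, the right end came first in most pairs. In 920 neighbouring pairs of a left and a right end with centres at most 30 kb apart, 871 (94.7% ± 0.611, interval 93.0% to 96.0%) had the end of a loop from the left followed by the start of a loop to the right, and 49 had the opposite order. With right ends shifted around each chromosome the share was 50.4% (SD 2.29; two-sided permutation p = 0.001, the smallest 1000 shifts can give). Shifted ends gave on average 243 pairs of the first order and 240 of the second, so the first was more frequent and the second less frequent than under shifting. No listed loop is shorter than 35 kb, so the opposite order here needs 2 loops that overlap at their ends. With centres up to 50 kb apart, where the pair can also be the ends of 1 short loop, the share was 80.9% (1347 of 1666 pairs), against 50.3% under shifting. Left and right ends also shared an anchor more often than shifted ones. Of 6260 merged left ends, 515 overlapped a right end (8.23% ± 0.416), against 4.86% (SD 0.288) under shifting (two-sided permutation p = 0.001, the smallest 1000 shifts can give). Ends of both kinds thus met more often than under shifting, although most shared anchors were one-sided. The shifts ran over whole chromosomes, empty stretches included. Differences in loop density along a chromosome can therefore raise the meeting of ends above the shifted level, and shorter shifts were not run for ends. The permutation of sides used only ends at shared anchors, so it does not show that partners on both sides are avoided. Where 2 loops met at a shared middle anchor, a further loop joined their outer anchors in 235 of 953 cases (24.7%, interval 21.95% to 27.5%). Where the middle anchors lay 25 to 100 kb apart, this held in 374 of 4331 cases (8.64%, interval 7.82% to 9.51%). The intervals treat cases as independent although they share anchors.

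**Figure D2:**
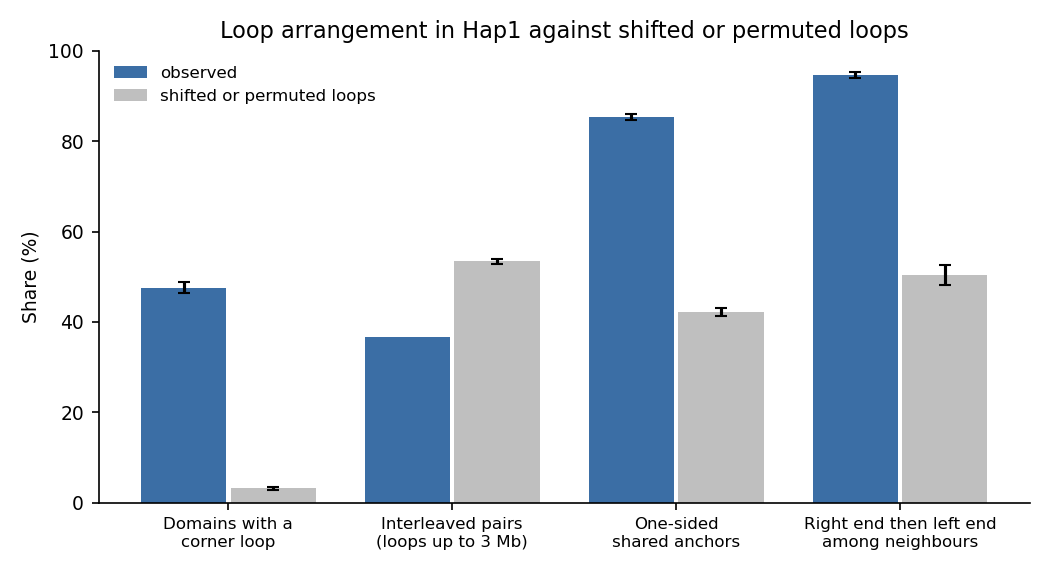
Observed shares in Hap1 (blue) and shares after shifting or permuting loops (grey) for 4 measures, in percent: contact domains with a corner loop, interleaved pairs among overlapping loops of at most 3 Mb, one-sided anchors among those in more than 1 loop, and neighbouring ends in the order right then left. Blue bars carry jackknife SEs except for the interleaved pairs, grey bars carry the SD over shifts or permutations, and the second pair is the only one where the observed share (36.6%) lies below the grey one (53.4%).

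The anchors in the most loops were spread over several chromosomes. Those with 7 loops were 61375001 to 61400000 on chromosome 10, with 4 partners to the right and 3 to the left at 185 to 840 kb, 55075001 to 55100000 on chromosome 4, with all 7 partners to the left at 200 to 1220 kb, and 88750001 to 88780000 on chromosome 4, with 2 partners to the right and 5 to the left. The loops of the 55075001 anchor had ratios of 2.09 to 5.38. Of the 9 anchors with 6 loops, 7 were named by order of position. Of these, the one from 176950001 to 177000000 on chromosome 2 had 3 partners on each side at 510 to 1400 kb, and the one from 87970001 to 87980000 on chromosome 5 had all 6 to the left. The anchor from 2020001 to 2030000 on chromosome 11 joined loops of 120 kb and of 69.25 Mb. The anchors from 234900001 to 234925000 on chromosome 1 and from 130875001 to 130900000 on chromosome 9 belonged only to loops of over 10 Mb.

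Chromosomes differed in loop density in step with domain density. Loops per Mb ran from 2.56 on chromosome 21 to 4.37 on chromosome 17, and domains per Mb from 1.18 on chromosome 4 to 2.83 on chromosome 22. Over the 23 chromosomes the densities correlated (Pearson's r = 0.844, permutation p = 1e-05; Spearman's rho = 0.806, permutation p = 1e-05; both the smallest 100000 permutations can give), and r was 0.820 without chromosomes 19 and 22, the 2 farthest from the median domain density. This was the only such relation computed, so p needed no adjustment. Both densities share a denominator, the covered length of the chromosome, which can raise r by an amount that was not tested. Chromosomes 17 and 19 had the shortest loops, with medians of 190 kb and 175 kb, and chromosome 13 the longest, with 400 kb. Chromosome 19 also had the lowest share of domains with a corner loop (35%, interval 27.1% to 43.5%) and chromosome 5 the highest (56.4%, interval 49.7% to 63.02%). Chromosome X had 2.92 loops per Mb, within 1 SD of the 22 autosomes (mean 3.35, SD 0.593), and 47.8% of its domains had a corner loop against an autosomal mean of 47.6% (SD 5.67). Its 1.27 domains per Mb lay below the autosomal mean of 1.85 by more than the SD of 0.468.

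**Figure D3:**
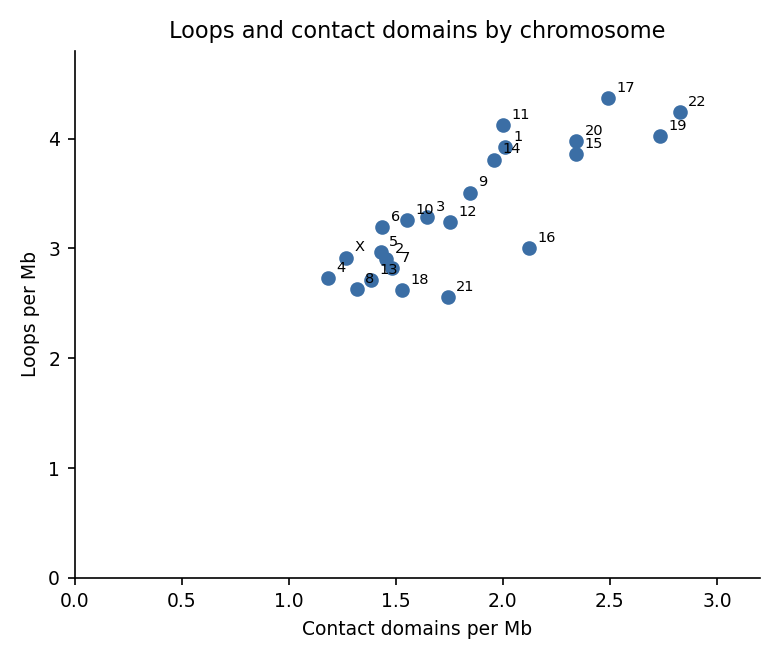
Loops per Mb against contact domains per Mb for the 23 chromosomes, one labelled point each. Density runs from 2.56 loops per Mb on chromosome 21 to 4.37 on chromosome 17, and Pearson's r is 0.844.

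Loops of at most 3 Mb were counted in windows of 5 Mb by their midpoints. The counts had a median of 14 and quartiles of 9 and 20 over the 555 windows that held any such loop or a domain. The window from 45000001 to 50000000 on chromosome 17 held the most, 42 loops, followed by 39 from 70000001 to 75000000 on chromosome 15, in a segment of raised background, and 37 from 50000001 to 55000000 on chromosome 12. At the other end, the window from 65000001 to 70000000 on chromosome 7 held 9 domains and 1 loop of at most 3 Mb, and none of those domains had a corner loop.

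The contacts expected around loops, compared with loops of the same length and anchor size, varied along chromosomes and were highest over a stretch of chromosome 15 from 63070001 to 89875000. The shift of its 136 loops was 0.95 ± 0.08 on the log2 scale (bootstrap SE), and with 25 kb anchors alone it was 1.70 ± 0.44 over 17 loops.

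**Figure D4:**
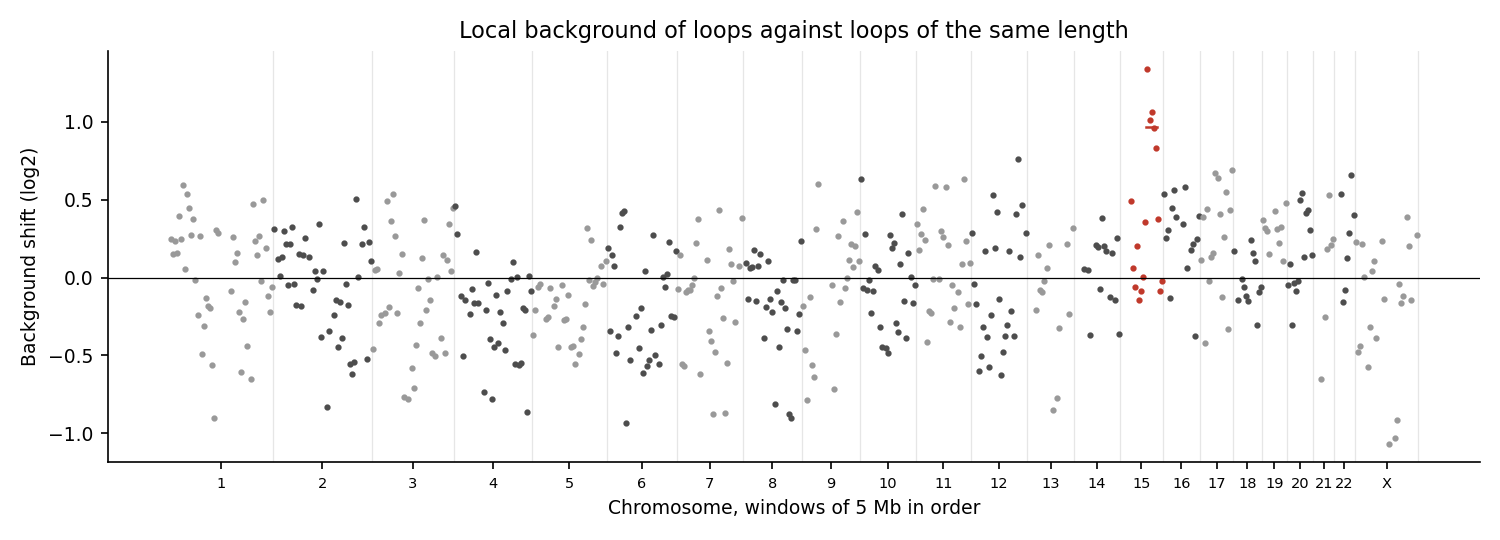
Median background shift (log2 donut expected contacts minus the fit on loop length) in windows of 5 Mb with at least 5 loops, along chromosomes 1 to 22 and X, with chromosome 15 in red. The red line marks the segment from 63070001 to 89875000 at its median of 0.97.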

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

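The corner share, the corner score difference, the interleaved share against its permuted level, the one-sided share, the order and sharing of loop ends and the density correlation kept their direction and side of the threshold under every alternative run. The corner share ran from 31.2% to 65.0% over matching distances, thresholds and length limits, the score difference from 0.102 to 0.131, and the one-sided share from 70.8% to 85.5%. Leaving out each chromosome moved the corner share between 47.1% and 48.02% and the interleaved share between 10.3% and 16.96%, the highest without chromosome 1. The length difference of domains did not keep its sign: -0.0435 within the smaller of 25 kb and 0.2 of the length, -0.0354 within 50 kb whatever the length, 0.0556 within the smaller of 100 kb and 0.2 of the length, and -0.00115 to 0.00682 leaving out each chromosome. A limit in kb alone favours short domains and a limit in proportion favours long ones by construction. The share of anchors in more than 1 loop was 40.4% with anchors within 10 kb merged and 25.3% with all FDR values at or under 0.01, where fewer loops remain; merging anchors that share at least 0.5 of the shorter one changed nothing, since anchors lie on a common grid. The log2 ratio of loops at domain corners differed by -0.0507 against the donut, -0.148 against the lower-left, -0.0778 against the horizontal and -0.0623 against the vertical background. The difference lost its call without loops over 3 Mb (-0.00556, permutation p = 0.598), and the cause was not tested. Of 26 loops picked for their ratio or length, 25 had a lower-left ratio, and 14 of these lay outside the counting interval of the donut ratio; the chromosome 12 loop of 98.4 Mb had none. Alternatives for the motif, start site and gene list comparisons were not run. No paired analysis was possible because the lists carry no replicates. The depth of the libraries limits which loops and domains could be called, and its effect cannot be measured from 1 call set.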

Other observations

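The local background of loops varied along the genome and was raised most on part of chromosome 15. The tests of an extra copy, of ordinary loops and of dense windows below were chosen after the result was seen, as were the values in this and the next paragraph. From 63070001 to 89875000 on chromosome 15, a width of 26.8 Mb, the donut background of 136 loops lay 0.95 ± 0.08 above the other loops of the genome on the log2 scale, or 1.93-fold (1.73 to 2.15). This stretch stood farthest from its chromosome among the 23 scans. It held 143 loops of at most 3 Mb, 5.33 per Mb, against 3.10 per Mb on the rest of chromosome 15 and 3.24 over the genome. It also held 93 contact domains, more than any of 1862 overlapping stretches of the same width elsewhere, which held at most 88. The median ratio of its loops, 2.63, lay within that of other stretches (2.54 at percentile 5 and 2.94 at percentile 95).

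Other chromosomes differed less. The median background shift of the 21 autosomes other than chromosome 15 was 0.05 on average (SD 0.15), and that of chromosome X was -0.10, within their range of -0.23 to 0.32. The stretch that stood farthest from the rest of chromosome X, from 78555001 to 106050000 with 27 loops, differed from it by -0.87.

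The raised background on chromosome 15 was set against 3 explanations. For the kind of loops called there, the shift was 0.91 ± 0.11 for 5 kb anchors, 0.94 ± 0.08 for 10 kb anchors and 1.70 ± 0.44 for 25 kb anchors. The fit on length for each anchor size had been taken out before the segment was picked for its shift. These values thus show a shift left at each anchor size after that fit, and are no separate test of this explanation. A dense region is argued against as the whole of the shift, since 38 windows of 5 Mb elsewhere with at least as many loops per Mb had a mean shift of 0.19 (SD 0.27, highest 0.67). These windows were narrower and, unlike the segment, not chosen for their shift, which may widen the gap by an amount that was not tested. A dense region stays open for part of the shift. The 1 other stretch of the same width with as many loops (shift 0.31) does not decide, being a single stretch set against one chosen for its shift. Hap1 is known from earlier work to carry an additional piece of chromosome 15, and an extra copy of the segment may account for the shift, since a doubling is a shift of 1 and the 3 background values lay at most 1.58 standard errors from it. The observed contacts of the same loops were shifted by only 0.74 ± 0.06, below a doubling by more than the error, so the extra copy stays open, on a segment chosen for its shift.

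Loops of over 3 Mb had a median ratio of 68.2 against 2.73 for shorter ones, and 3 explanations were weighed. The list holds no loop with fewer than 12 contacts, so low expected values at long distances by themselves force high ratios. How much of the gap this makes up was not tested. Of the 67, 35 had another long loop within 1.5 Mb at both ends, against a mean of 20.8 and a highest count of 29 with second anchors permuted (one-sided permutation p = 0.001, the smallest 1000 permutations can give), so segments joined in the Hap1 genome may account for part of them, although families of near-identical sequences could gather in the same way. Reads shared between such sequences stay open, since 14 of the 32 loops without a neighbour (43.8%, interval 26.4% to 62.3%) had both flanking backgrounds under 0.05 of the observed contacts, an interval that spans both outcomes. Of the 8267 shorter loops, 13 also had both flanking backgrounds under 0.05 of the observed contacts, and shared reads were not tested for these. In 16 of the 67 the larger flanking background was at least 3 contacts and at least 10 times the smaller, as in 0 of the 8267 shorter loops. Shorter loops had contacts on both flanks, with medians of 0.386 of the observed contacts for the smaller and 0.457 for the larger. Flanks that differ 10 times could hardly arise among them, so this comparison does not decide on ordinary loops for the 16. The 16 lay in a few pairs of regions on chromosomes 1, 8, 9 and 17. Most of them shared an end with others of the 16, so they are not 16 independent cases. For the others ordinary loops stay open as well. Of the 67, 83.6% had a smaller flanking background, relative to the observed contacts, below the 1st percentile of shorter loops. But few contacts are expected at such distances.

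Some long loops joined the same pairs of regions. On chromosome 9, 6 loops joined 92190001 to 93975000 with the bin from 130875001 to 130900000, and on chromosome 1, 4 loops joined 85975001 to 86000000 with 145275001 to 145725000. On chromosome 8, 3 loops joined 101965001 to 102320000 with 128750001 to 128760000.

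At the main matching distance most contact domains had no corner loop, and 2 explanations were weighed. The majority depends on that distance, since 52.4% of domains had a corner loop within the smaller of 100 kb and 0.2 of the length, 51.9% within 50 kb and 65.0% within 100 kb. Loops missed by the matching distance stay open: matching within 100 kb raised the excess over shifted loops by 6.51 percentage points, under the 10 set in advance, but to 50.9%, which ends the majority. Too few contacts to call the loop stay open as well: on the chromosome 15 segment, with its raised contacts, the share with a corner loop was 41.9% (39 of 93, interval 31.8% to 52.6%), above only 17.1% of the other stretches, but domains are called from the same contacts and the segment also held more of them than any other stretch, so the share does not decide. Neither of 2 values chosen after this result was seen can decide. The 39 domains with a corner loop were more than in 99.2% of the stretches, but the segment held 93 domains against a median of 37. Among the 46 domains with a score at or above the median the share was 43.5% (interval 28.9% to 58.9%), above only 4.51% of 1753 stretches. The share among these 46 was thus not raised on the segment. But its interval is wide, and the score belongs to domains called from the same contacts.

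Only the Hap1 lists were used for these patterns, so no comparison between groups bears on them.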
